A study of Mus musculus with 12 samples.

How the data were processed

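RNA was sequenced from whole lungs of mice carrying MMTV-PyMT, a transgene in which the mouse mammary tumour virus promoter drives an oncogene, the polyoma virus middle T antigen, in mammary epithelium, so that mammary tumours form and seed the lung. Per the labels, tissue was taken at 4.5 months and came from 3 genotypes, all with an MMTV-driven Cre recombinase: wild type (WT), a conditional C3 knockout (C3 KO) and a conditional S1pr1 knockout (S1pr1 KO), with 4 libraries each. The samples were kept in RNAlater, the RNA was extracted with QIAzol and libraries were made by a commercial sequencing provider with Illumina protocols, per the labels' protocols. Group membership was taken from the sample titles and genotype labels. Replicate numbers within a group followed the order of deposition and pair nothing across groups. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples.

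The deposited table of counts held whole-number read counts for 56748 genes in 12 libraries, with 1 column per library and no pooling. CASAVA and STAR, with the builds GRCm39 and mm39, are named in the submitters' processing notes without versions. The tool that counted reads per gene, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may have been split between genes. The deposited FPKM table gave the same libraries per kilobase of the listed gene length and scaled to an effective library size, whose ratio to the TMM effective size ranged from 1.00 to 1.01. FPKM values were used only in an alternative. Gene names, biotypes and coordinates are those of the deposited table, on GRCm39. A reference annotation of another build was not used here.

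Total counts per library ranged from 32274797 to 53063470. Pearson correlation of log2 CPM between libraries ranged from 0.963 to 0.988, and the chi-square per degree of freedom between libraries of a group was at least 13.3, so no pair differed by as little as sampling noise. The first principal components held 23.3% and 15.7% of the variance. No sequencing batch or date stands in the labels.

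Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 20229 genes, libraries were scaled with TMM, and a quasi-likelihood model with a mean for each of the 3 groups was fitted to the 12 libraries (9 residual degrees of freedom). The comparisons were C3 KO against WT, S1pr1 KO against WT, and S1pr1 KO against C3 KO. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, with a threshold of 0.05. In what follows an edgeR adjusted p is this quasi-likelihood p after Benjamini-Hochberg adjustment, a fold change is a log2 value with its standard error (SE), and levels are CPM values (read counts relative to the TMM-scaled library total), as mean ± SD. For edgeR fold changes the SE was back-calculated, as the absolute log2 value divided by the square root of the quasi-likelihood F statistic.

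Gene lists for 42 cell types and pathways were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Of the listed genes, 9 were not in the table. A list score is the mean log2 CPM of the tested members in a library. Scores were compared by a two-sided exact permutation test, for which 4 libraries against 4 allow a smallest p of 0.0286. These permutation p-values were not adjusted over the lists.

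The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule always named C3, S1pr1, C3ar1, C5ar1, Nlrp3 and Il1b. For each comparison it took up to 10 rising and 10 falling protein coding genes of largest fold change with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol that is not a clone name and no overlap between the groups, or, if none qualified, the 5 of lowest p. From each list that passed, and from 5 lists in any case, it took up to 4 members of lowest p, and it added genes called in both knockouts. Of the 253 pairs of gene and comparison this allowed, the text uses only part, chosen after the values had been seen, although every gene of the largest rises and falls is given. The pseudogenes, their parent genes and Trdc were also chosen after their values were seen.

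The alternatives planned were DESeq2 1.42.0, limma voom with sample quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with at least 0.5 FPKM in 4 libraries, RLE and upper-quartile scaling, no filter or a filter of 1 CPM in 4 libraries, a robust fit, fits of only the groups compared, a fold threshold, list scores for mammary epithelium and proliferation as covariates, and leaving out each library in turn. Chosen after seeing the data were the covariates for the ciliated cell and cardiomyocyte scores, the restriction to protein coding genes, and leaving out 2 libraries together, either the library labelled C3 KO 4 with the library labelled S1pr1 KO 2, or WT 2 with the library labelled S1pr1 KO 2.

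The steps were tested on simulated data drawn from the means and library sizes of the tested genes, of which 19911 passed the filter again. Known changes were placed in the S1pr1 KO against WT comparison, in randomly drawn genes and, apart from these, in the T cell list. Of the randomly drawn genes, 18 of 67 (26.9%) were recovered at 1.5-fold, 35 of 66 (53.0%) at 2-fold and 57 of 65 (87.7%) at 4-fold, and 4 of all 123 calls, which include T cell list genes, fell on unchanged genes. Camera with the preset correlation called the T cell list and 1 other list, and some lists share genes with the T cell list. Each gene was drawn independently, without the co-variation of genes in real libraries. The simulation therefore could not test the preset correlation or the rate of false list calls in these data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.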

Results

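Whole-lung RNA was profiled in 12 libraries from MMTV-PyMT mice, with 4 libraries each of WT, C3 KO and S1pr1 KO lung. The title of the series states the question: how conditional loss of the complement component C3 or of the sphingosine-1-phosphate receptor S1pr1 bears on lung metastasis in this model of mammary cancer. Total counts were 42821425, 36603903, 35240009 and 36665713 in the WT libraries, 34869987, 34131299, 36392193 and 39263550 in the C3 KO libraries, and 53063470, 40949172, 36337246 and 32274797 in the S1pr1 KO libraries. The number of genes with at least 1 count lay between 26691 and 28277, and the most abundant transcript, Scgb1a1 of airway club cells, took between 1.31% and 2.69% of each library.

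C3, the central complement protein (ENSMUSG00000024164, chromosome 17 from 57510970 to 57535136), was at 1025, 787, 903 and 799 CPM in the WT libraries. It was at 475, 465 and 601 CPM in C3 KO 1, C3 KO 2 and C3 KO 3 and at 1416 CPM in the library labelled C3 KO 4, which lay above every WT library. S1pr1, a receptor for sphingosine-1-phosphate that guides lymphocyte exit from lymphoid organs and is abundant in endothelium (ENSMUSG00000045092, chromosome 3 from 115504082 to 115508721), was at 295, 491, 319 and 330 CPM in WT. It was at 132, 142 and 154 CPM in S1pr1 KO 1, 3 and 4 and at 366 CPM in the library labelled S1pr1 KO 2, which lay within the WT range. Neither targeted gene passed the test: the log2 fold change of C3 in C3 KO was -0.25 (SE 0.30, edgeR adjusted p = 0.813) and that of S1pr1 in S1pr1 KO was -0.85 (SE 0.29, edgeR adjusted p = 0.153). Without the library labelled C3 KO 4 the C3 value was -0.77 and passed, and without the library labelled S1pr1 KO 2 the S1pr1 value was -1.33 and passed, but libraries chosen by the level of the targeted gene make these values circular. Per the labels Cre was driven by the MMTV promoter, which is active mainly in mammary epithelium, so levels in whole lung need not show a deletion. The targeted gene nevertheless lay below every WT library in C3 KO 1, 2 and 3 and in S1pr1 KO 1, 3 and 4. The promoter's main site by itself thus does not account for the difference between libraries of a group, and where Cre acted was not tested. These levels alone do not tell whether a label is wrong. Every direction given below for a knockout group includes the libraries labelled C3 KO 4 and S1pr1 KO 2 as labelled. In the other knockout, C3 (-0.10 in S1pr1 KO) and S1pr1 (-0.26 in C3 KO) did not pass, with edgeR adjusted p = 0.90 and 0.803. The C3 value was -0.019 without WT 1, -0.035 without S1pr1 KO 4 and -0.17 without the library labelled S1pr1 KO 2, and the S1pr1 value was -0.060 without WT 2.

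**Figure D1:**
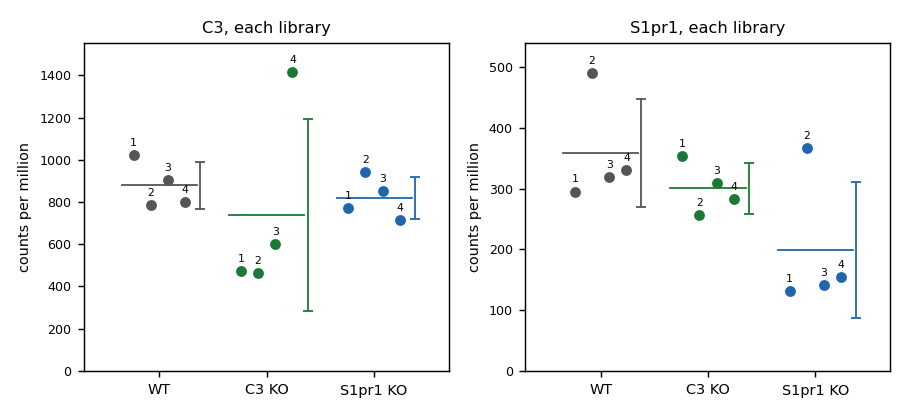
Levels of C3 and S1pr1 in CPM (vertical axis, linear from 0) for the 12 libraries by group; each point is a library with its replicate number, the horizontal line is the mean of 4 libraries and the bar is ± 1 SD. C3 reached 1416 CPM in the library labelled C3 KO 4 and S1pr1 reached 366 CPM in the library labelled S1pr1 KO 2, against 132 to 154 CPM in the other S1pr1 KO libraries.

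In C3 KO against WT, the transcripts that passed were a mitochondrial gene and a pseudogene. Gm28438, an unprocessed pseudogene (ENSMUSG00000101939, chromosome 1 from 24651856 to 24652200), rose from 0.701 ± 0.14 to 8.73 ± 1.82 CPM (SD, n = 4 each), a log2 fold change of 3.63 (SE 0.27, edgeR adjusted p = 0.000171). The mitochondrially encoded complex I subunit mt-Nd3 (ENSMUSG00000064360, chromosome MT from 9459 to 9806) fell from 6.16 ± 0.923 to 0.902 ± 0.579 CPM, a log2 fold change of -2.77 (SE 0.36, edgeR adjusted p = 0.0472). Mitochondrial genes have nuclear copies with which reads can be shared, so both values are uncertain. The complement peptide receptors C3ar1 (0.31) and C5ar1 (0.07) did not pass, nor did the inflammasome sensor Nlrp3 (0.14) and the cytokine Il1b (-0.77), the lowest edgeR adjusted p being 0.641. Il1b was at -0.20 without WT 1, and C3ar1 was at 0.18 without WT 3 and 0.17 without the library labelled C3 KO 4. In all, 2 of 20229 genes passed in edgeR, and 2217 had an unadjusted p under 0.05 where chance gives 1011. DESeq2 called 155 (99 up, 56 down) and limma voom with quality weights 21 (4 up, 17 down). The count was 1 without WT 1, WT 2, WT 3, WT 4, S1pr1 KO 1, S1pr1 KO 3, S1pr1 KO 4 or the library labelled S1pr1 KO 2, with mt-Nd3 no longer passing, and it was 32 without the library labelled C3 KO 4. Without C3 KO 2 the count was 2, but mt-Nd3 was not among them.

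Red cell transcripts were higher and skeletal muscle transcripts lower in C3 KO as lists, although no single member passed over all genes in edgeR. Of 19 erythroid genes 18 were higher in C3 KO, with a median log2 fold change of 1.57, and 10 rose when adjusted over the list alone (camera adjusted p = 0.000227, adjusted p = 0.997 with an estimated correlation). Members by value were the globins Hbb-bt (3.27, SE 0.98), Hba-a1 (2.29, SE 0.73) and Hbb-bs (2.24, SE 0.70), and the erythroid score was 7.35 in C3 KO 3 against 4.26 to 5.53 in the other C3 KO libraries. All 13 skeletal muscle genes were lower (median -1.85, camera adjusted p = 0.0353, adjusted p = 0.997 with an estimated correlation, 0 called adjusted over the list alone), with Acta1 at -6.32 (SE 2.38) and Myh1 at -5.41 (SE 2.08). The skeletal muscle score was 4.59 in WT 2 against 0.30 to 1.08 in the other WT libraries. Erythroid genes were no longer called without C3 KO 3 (camera adjusted p = 0.102), nor skeletal muscle genes without WT 2 (0.855), with a filter of 1 CPM in 4 libraries (0.115) or with the ciliated score as a covariate (0.192). Without C3 KO 3 the values of Hbb-bt, Hba-a1 and Hbb-bs were 0.99, 0.82 and 0.82, and without WT 2 those of Acta1 and Myh1 were -1.71 and -0.77. Exact permutation of the list scores gave p = 0.20 for erythroid and 0.143 for skeletal muscle genes.

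The list of ciliated cell genes was higher in C3 KO in 26 of 28 members (median 0.16, camera adjusted p = 0.00149), for example Rsph4a (0.39, SE 0.15) and Dnah11 (0.39, SE 0.15), parts of the motile cilium. Cardiomyocyte genes were higher in 20 of 24 members (median 0.28, camera adjusted p = 0.0353), with the calcium channel Ryr2 at 0.97 (SE 0.39). MHC class I genes were lower in 12 of 15 members (median -0.17, camera adjusted p = 0.0258), 2 of which fell adjusted over the list alone, with the class I genes H2-Q7 at -1.10 (SE 0.21) and H2-D1 at -0.29 (SE 0.08). Reads of this gene family can be shared. Immediate early genes were lower in 24 of 28 members (median -0.34, camera adjusted p = 0.0421), with the transcription factors Klf2 at -0.87 (SE 0.31) and Klf4 at -0.79 (SE 0.31). No member of these 4 lists passed over all genes in edgeR, and adjusted over the list alone 0 passed outside the MHC class I list. For each of the 4 lists adjusted p = 0.997 with an estimated correlation. Exact permutation of the list scores gave p = 0.457 for ciliated, 0.543 for cardiomyocyte, 0.286 for MHC class I and 0.343 for immediate early genes. Ciliated genes were not called without WT 1 (camera adjusted p = 0.264) or the library labelled C3 KO 4 (0.352). Cardiomyocyte genes were not called without WT 1 (0.766), C3 KO 1 (0.249), C3 KO 3 (0.0916) or the library labelled C3 KO 4 (0.110). MHC class I genes were not called without WT 1 (0.282), C3 KO 3 (0.0636) or the library labelled C3 KO 4 (0.138), nor immediate early genes without WT 1 (0.264), WT 2 (0.325), C3 KO 2 (0.0959) or C3 KO 3 (0.398). With the ciliated score as a covariate cardiomyocyte (0.192) and MHC class I genes (0.420) were not called, nor with the cardiomyocyte score MHC class I (0.130) and immediate early genes (0.149). Rsph4a and Dnah11 were at 0.24 and 0.25 without the library labelled C3 KO 4.

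Complement genes were not called in C3 KO (31 members, median 0.03, adjusted p = 0.787), and the camera direction was down although the median was above 0. Nor were the S1P and ceramide (37 members, median -0.02, camera adjusted p = 0.992), inflammasome (25 members, -0.05, 0.962), mammary epithelial (27 members, -0.20, 0.716) or proliferation lists (40 members, 0.04, 0.992). Adjusted over the list alone, 0 members of these 5 lists passed in edgeR, as over all genes. By value, the complement protease Masp1 was at -0.56 (SE 0.21), the ceramide glucosyltransferase Ugcg at -0.25 (SE 0.09), and the purinergic receptor P2rx7 at 0.24 (SE 0.09). The oestrogen receptor Esr1 was at -0.34 (SE 0.14), the receptor Erbb3 at 0.30 (SE 0.11) and the replication clamp Pcna at -0.08 (SE 0.07). None of these 6 passed, with the lowest edgeR adjusted p at 0.368. Without WT 4 Masp1 was at -0.32 and Pcna at -0.041, without C3 KO 1 Pcna was at -0.042, and without the library labelled C3 KO 4 Erbb3 was at 0.17 and Pcna at -0.13. Of lists whose median or mean and camera direction differed in sign, none was called, among them neutrophil (median 0.14, mean 0.13, direction down) and mitochondrial genes (median 0.01, mean -0.38, direction down). Of the 42 lists, 6 were called with the preset correlation (3 up, 3 down) and 0 with an estimated correlation or by fry in one direction. The number of called lists was 3 without WT 1 and 11 without WT 3.

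In S1pr1 KO against WT, receptors of natural killer cells and other cytotoxic lymphocytes were higher. The Ly49 receptor Klra9 (ENSMUSG00000033024) rose by log2 2.15 (SE 0.33, edgeR adjusted p = 0.0145), from 0.880 ± 0.302 to 3.94 ± 0.117 CPM (SD, n = 4). Klra8 (ENSMUSG00000089727) rose by 2.07 (SE 0.38, edgeR adjusted p = 0.0309) and Klrc2 by 1.89 (SE 0.40, edgeR adjusted p = 0.0440). The scavenger receptor Scart1 (ENSMUSG00000025461, chromosome 7 from 139798180 to 139811058) rose by 2.39 (SE 0.27, edgeR adjusted p = 0.00716), from 2.94 ± 0.566 to 15.4 ± 4.58 CPM. Ly49 and Klrc genes are families of similar copies, so their reads can be shared. All 19 genes of the NK and cytotoxic list were higher (median 0.80), of which 1 rose over all genes and 11 adjusted over the list alone. The activating receptor Klrk1 (1.10, SE 0.28, edgeR adjusted p = 0.0685) and granzyme Gzmb (1.10, SE 0.31, edgeR adjusted p = 0.0892) did not pass over all genes. The list was called by camera (adjusted p = 1.49e-06, adjusted p = 0.710 with an estimated correlation), and its score was 2.60 ± 0.14 in S1pr1 KO against 1.80 ± 0.49 in WT (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows).

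T and B lymphocyte genes were lower. All 28 T cell genes had a negative fold change (median -0.86). With the ciliated score as a covariate 21 were lower and 7 higher (median -0.29). The co-receptor Cd4 fell from 7.54 ± 1.77 to 3.53 ± 0.404 CPM (-1.10, SE 0.19, edgeR adjusted p = 0.0276) and Cd6 fell by 1.73 (SE 0.35, edgeR adjusted p = 0.0389). These 2 fell over all genes and 20 adjusted over the list alone. Ccr7, the homing receptor of naive T cells, was at -1.38 (SE 0.33, edgeR adjusted p = 0.0605) and Cd3d of the T cell receptor complex at -1.26 (SE 0.30, edgeR adjusted p = 0.0623). The list was called by camera (adjusted p = 3.14e-15, adjusted p = 0.645 with an estimated correlation), with a score of 1.94 ± 0.50 against 2.86 ± 0.27 in WT (exact permutation p = 0.0571). Of 21 B cell genes 20 were lower (median -1.03, camera adjusted p = 9.82e-08, adjusted p = 0.710 with an estimated correlation). With the ciliated score as a covariate the B cell list was not called (camera adjusted p = 0.481), with 8 members lower, 13 higher and a median of 0.066. Without the covariate no B cell gene passed over all genes, and adjusted over the list alone 4 fell and Vpreb3 (0.60, SE 0.19) rose. Cd79a, a chain of the B cell receptor complex, was at -1.43 (SE 0.47). The B cell score was 2.93 ± 0.67 against 3.99 ± 0.46 (exact permutation p = 0.0571), and S1pr1 KO 3 (3.93) lay within the WT range of 3.33 to 4.36. Thymocyte genes, some shared with the T cell list, were lower in 10 of 12 members (median -0.51, 1 over all genes, 5 adjusted over the list alone, camera adjusted p = 0.000442, adjusted p = 0.645 with an estimated correlation), with Cd8b1 at -1.85 (SE 0.54). Without genes of other lists it was not called (camera adjusted p = 0.201). The thymocyte score had an exact permutation p = 0.0571.

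**Figure D2:**
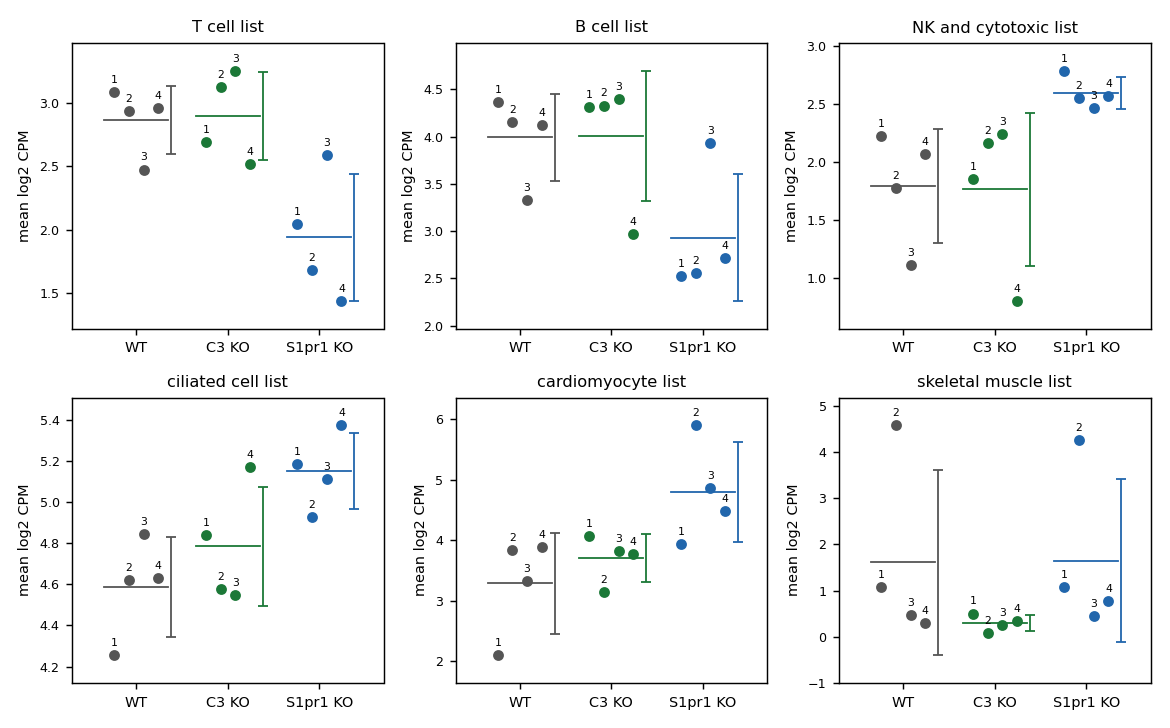
List scores (mean log2 CPM, vertical axis) of 6 lists for the 12 libraries by group; each point is a library with its replicate number, the line is the mean of 4 libraries and the bar is ± 1 SD. NK scores were 2.60 ± 0.14 in S1pr1 KO and 1.80 ± 0.49 in WT, T cell scores were 1.94 ± 0.50 and 2.86 ± 0.27, and the skeletal muscle score stood apart in WT 2 (4.59) and in the library labelled S1pr1 KO 2 (4.27).

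Airway genes were higher in S1pr1 KO. All 28 ciliated cell genes had a positive fold change (median 0.55, camera adjusted p = 3.14e-15, adjusted p = 0.678 with an estimated correlation), 4 rose over all genes and 20 adjusted over the list alone. Those 4 were Ccdc153 (0.89, SE 0.16, from 57.3 ± 11.7 to 106 ± 14.2 CPM), Cfap43 (0.85, SE 0.19), Mlf1 (0.78, SE 0.15) and Ccdc113 (0.64, SE 0.14), with edgeR adjusted p from 0.0295 to 0.0488. The ciliated score was 5.15 ± 0.18 against 4.59 ± 0.24 (exact permutation p = 0.0286). Club cell genes were higher in 18 of 22 members (median 0.70, 0 over all genes, 3 adjusted over the list alone, camera adjusted p = 0.00240, adjusted p = 0.718 with an estimated correlation), with the antimicrobial lectin Reg3g at 2.72 (SE 0.70) and Gsto1 at 0.99 (SE 0.25). Club cell genes were not called without WT 1 (camera adjusted p = 0.132) or with the ciliated (0.116) or cardiomyocyte score (0.907) as a covariate. The club cell score had an exact permutation p = 0.114.

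Cardiomyocyte genes, which mouse lung also expresses in the muscle sleeves of its large veins, were higher in 22 of 24 members (median 1.66, camera adjusted p = 3.22e-11, adjusted p = 0.710 with an estimated correlation). The calcium release channel Ryr2 rose from 13.5 ± 5.14 to 48.8 ± 23.3 CPM (1.86, SE 0.39, edgeR adjusted p = 0.0436) and the sarcomere protein Myoz2 rose by 1.72 (SE 0.37, edgeR adjusted p = 0.0464), and 22 rose and 1 fell adjusted over the list alone. Mybpc3 (2.56, SE 0.58) and Tnni3 (1.62, SE 0.36) did not pass over all genes (edgeR adjusted p = 0.0535 and 0.0519). Scores were 4.80 ± 0.83 against 3.29 ± 0.83 (exact permutation p = 0.0286). The 10 protein coding genes of largest rise under the rule fixed for named genes held Scart1, Klra9, Klra8 and Klrc2, given above. The others were the potassium channel genes Kcnj3 (2.79, SE 0.61) and Kcng2 (2.48, SE 0.55), the cadherin Cdh26 (2.52, SE 0.54), the iron hormone Hamp (2.24, SE 0.32), the glutamate transporter Slc17a7 (2.16, SE 0.39) and Tmc5 (2.10, SE 0.44), with edgeR adjusted p from 0.0145 to 0.0486.

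Falls of the 10 protein coding genes chosen by the same rule ranged from -5.50 to -1.29. Gbp2b, an interferon-induced GTPase (ENSMUSG00000040264, chromosome 3 from 142300608 to 142324940), fell from 20.7 ± 5.25 to 0.452 ± 0.139 CPM (-5.50, SE 1.15, edgeR adjusted p = 0.0429), and mt-Nd3 fell by 3.16 (SE 0.37, edgeR adjusted p = 0.00716). Lhfpl3 fell by 3.94 (SE 0.72), the acute-phase protein gene Orm2 fell by 3.33 (SE 0.68), the sulfatase gene Arsj fell by 2.15 (SE 0.33) and Amd2 fell by 1.93 (SE 0.41). The transporter gene Abca17 fell by 1.42 (SE 0.22), Ccdc184 fell by 1.30 (SE 0.18) and Fam124b fell by 1.29 (SE 0.28). The edgeR adjusted p of these 7 lay from 0.0145 to 0.0462, and Cd6 is given above. On a log2 CPM scale from 0 (WT mean) to 1 (S1pr1 KO mean), Gbp2b lay at 1.05, -0.076, 0.95 and 0.039 in the C3 KO libraries in numbered order. In the same order Orm2 lay at 0.037, 1.08, -0.03 and 0.77, Arsj at 0.93, 0.09, -0.042 and 0.17, and Lhfpl3 at 0.43, 1.07, 1.18 and 0.30. Part of the C3 KO libraries thus lay at the S1pr1 KO level, so these falls were not particular to S1pr1 KO. Among the named rises, Tmc5 lay at 0.574, 0.394, -0.084 and 1.035 and Cdh26 at 0.675, 0.204, 0.078 and 0.725. Klra9 lay at 0.261, 0.607, 0.446 and -0.199, and Klra8 at 0.162, 0.529, 0.332 and -0.489. Hamp, Slc17a7, Kcnj3 and Kcng2 also had C3 KO libraries on both sides of the midpoint, while Scart1 did not. Gm28438 rose by 3.19 (SE 0.27, edgeR adjusted p = 0.000676). Of the 274 genes called, 204 were protein coding and 41 were pseudogenes of any kind. Processed pseudogenes made 33 calls among 924 tested, 30 of them falls, against 241 among the 19305 other genes (Fisher's exact test, odds ratio 2.93, 95% interval 1.96 to 4.26, p = 3.85e-07). Examples, chosen after their values were seen, were Atp6v0c-ps2 (-6.48, SE 1.39), Rnps1-ps (-6.22, SE 1.27) and Gm15459 (-3.96, SE 0.71), with edgeR adjusted p from 0.0309 to 0.0462. Pseudogene reads can be shared with parent genes.

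**Figure D3:**
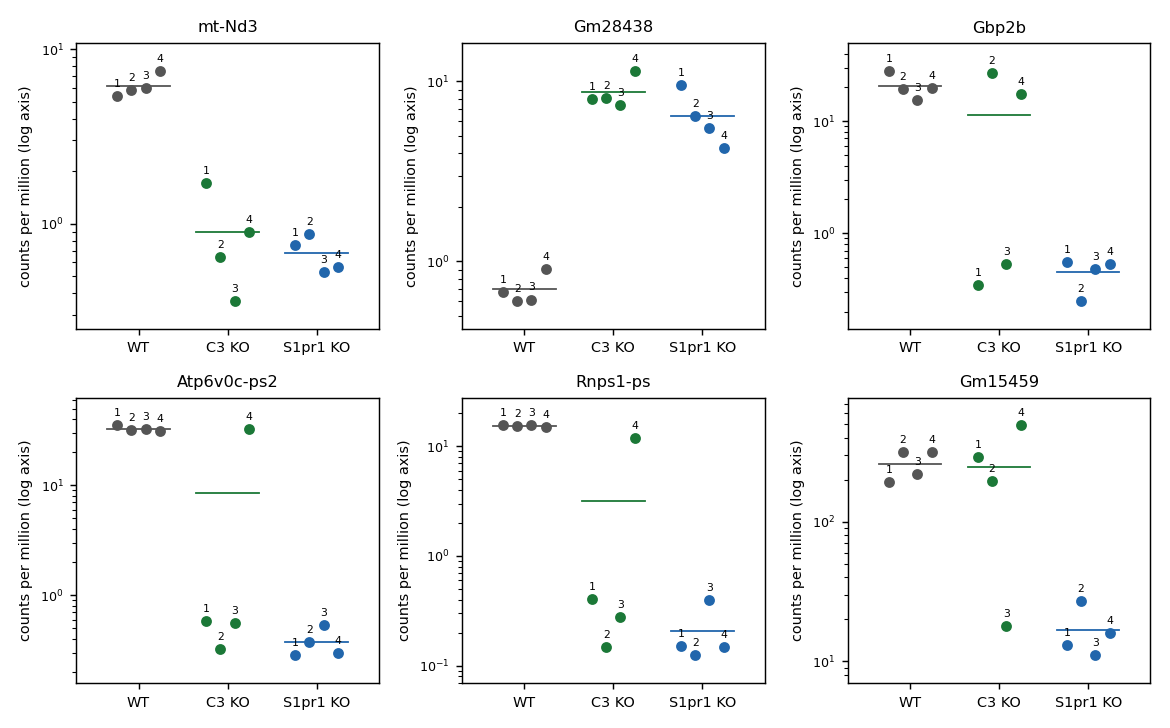
Levels in CPM (log axis) of 6 transcripts with large changes for the 12 libraries by group; each point is a library with its replicate number and the line is the mean of 4 libraries. For Atp6v0c-ps2 the WT libraries lay between 31.5 and 35.4 CPM and the S1pr1 KO libraries between 0.284 and 0.531 CPM, while the C3 KO libraries were at 0.578, 0.322, 0.555 and, in the library labelled C3 KO 4, 32.7 CPM.

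Further lists were called in S1pr1 KO. Immediate early genes were lower in 27 of 28 members (median -0.61, camera adjusted p = 1.18e-05, adjusted p = 0.710 with an estimated correlation), with Zfp36 at -0.92 (SE 0.42) and Socs3 at -0.63 (SE 0.24). Endothelial genes were lower in 28 of 34 members (median -0.14, camera adjusted p = 0.000708, adjusted p = 0.710 with an estimated correlation). Gpihbp1, which holds lipoprotein lipase on capillaries, fell by 0.45 (SE 0.09, edgeR adjusted p = 0.0440) and was the 1 member to pass over all genes and adjusted over the list alone. Plvap was at -0.55 (SE 0.17). MHC class II genes were lower in 11 of 13 members (median -0.24, camera adjusted p = 0.0115, adjusted p = 0.718 with an estimated correlation), and the chaperone H2-Oa, the 1 member to pass either way, fell by 1.07 (SE 0.18, edgeR adjusted p = 0.0220). Inflammasome genes were lower in 21 of 25 members (median -0.16, camera adjusted p = 0.00517, adjusted p = 0.710 with an estimated correlation), with Il18r1 at -0.50 (SE 0.12). Adjusted over the list alone 1 inflammasome member rose and 1 fell, and no immediate early or mesothelial member passed. Neutrophil genes were lower in 20 of 22 members (median -0.64, camera adjusted p = 0.00563, adjusted p = 0.778 with an estimated correlation), with Trem1 at -1.21 (SE 0.39) and 1 rise adjusted over the list alone. Mesothelial genes were lower in 11 of 14 members (median -0.23, camera adjusted p = 0.0319, adjusted p = 0.778 with an estimated correlation), with Slpi at -0.93 (SE 0.30). Calls were lost without WT 1 for MHC class II (0.193), inflammasome (0.132) and mesothelial genes (0.199), without the library labelled S1pr1 KO 2 for neutrophil genes (0.120), and without S1pr1 KO 1 (0.206) or S1pr1 KO 4 (0.105) for mesothelial genes. With the ciliated and the cardiomyocyte score as covariates, in that order, they were lost for MHC class II (0.116 and 0.441), inflammasome (0.898 and 0.788) and neutrophil genes (0.890 and 0.891), and with the ciliated score for endothelial (0.799) and mesothelial genes (0.898). Zfp36 was at -1.64 and passed without S1pr1 KO 1 (edgeR adjusted p = 0.0411), and Slpi was at -0.44 without WT 2.

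Proliferation genes were higher in 37 of 40 members in S1pr1 KO (median 0.26, camera adjusted p = 0.00262, adjusted p = 0.864 with an estimated correlation), with the mitotic kinase Melk at 0.85 (SE 0.30). Mammary epithelial genes were higher in 19 of 27 members (median 0.24, camera adjusted p = 0.0334, adjusted p = 0.710 with an estimated correlation), with the progesterone receptor Pgr at 0.56 (SE 0.20). No member of either list passed, over all genes in edgeR or adjusted over the list alone. Exact permutation of the list scores gave p = 0.371 for proliferation and 0.314 for mammary genes. Proliferation was not called without WT 3 (0.0655), S1pr1 KO 3 (0.112) or S1pr1 KO 4 (0.260), nor the mammary list without WT 4 (0.115) or S1pr1 KO 4 (0.116). With the ciliated score as a covariate neither was called (0.327 and 0.261), and the mammary list was not called with the cardiomyocyte score (0.201) or a filter of 1 CPM in 4 libraries (0.101). The S1P and ceramide list was not called (8 of 37 members higher, median -0.06, camera adjusted p = 0.0657), although the lymphocyte receptor S1pr4 fell by 0.62 (SE 0.13, edgeR adjusted p = 0.0466). Adjusted over the list alone 1 of its members rose and 3 fell, and its score was lower by 0.073 (two-sided exact permutation p = 0.0286). Complement genes were not called (31 members, median -0.05, camera adjusted p = 0.372, 0 members passing in edgeR or adjusted over the list alone), with Clu at 0.30 (SE 0.13). C3ar1 (-0.04), C5ar1 (-0.24), Nlrp3 (-0.36) and Il1b (-1.24, SE 0.58) did not pass, the lowest edgeR adjusted p being 0.279. Without WT 1 Il1b was at -0.68, Nlrp3 at -0.23 and C5ar1 at -0.12, and without WT 3 C5ar1 was at -0.37. Skeletal muscle genes were not called and differed in sign between list median (-0.20), mean (-0.18) and camera direction (up, adjusted p = 0.778), as did mitochondrial genes (median 0.19, mean -0.32, direction up), of which 6 rose and 2 fell adjusted over the list alone. Mitochondrial genes took 1.56% to 1.85% of the counts in S1pr1 KO against 1.37% to 1.48% in WT (two-sided exact permutation p = 0.0286). Their list score went the other way, at 6.62 ± 0.16 in S1pr1 KO against 6.93 ± 0.17 in WT (two-sided exact permutation p = 0.0286).

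Of 20229 genes, 274 were called in S1pr1 KO against WT (166 up, 108 down), 130 of them with an absolute log2 fold change of at least 1. An unadjusted p under 0.05 was found for 3651 genes, where chance gives 1011. DESeq2 called 1224 and limma voom with quality weights 928. The count was 45 without WT 1, 51 without WT 2, 64 without WT 3 and 5 without WT 4. It was 80 without S1pr1 KO 1, 128 without the library labelled S1pr1 KO 2, 60 without S1pr1 KO 3, 2 without S1pr1 KO 4 and 571 without the library labelled C3 KO 4. Of 40 called genes named for this comparison, 29, 27, 24 and 37 were no longer called without WT 1, WT 2, WT 3 and WT 4, and 24, 22, 24 and 38 without the 4 libraries labelled S1pr1 KO, each in numbered order. Without C3 KO 1, C3 KO 2 or C3 KO 3, 13, 10 and 3 were no longer called, and without the library labelled C3 KO 4, 0. Of the 40, only Gm28438 and Scart1 passed in edgeR without each of the 12 libraries in turn. With the cardiomyocyte score as a covariate 1 gene was called, with 39 of the 40 named calls lost, and with the ciliated score 37. Both scores were higher in every S1pr1 KO library than in every WT library. As covariates they therefore take up much of the group difference, so calls of genes or lists lost with them do not show a cause. Of the 42 lists, 15 were called with the preset correlation (6 up, 9 down), 0 with an estimated correlation and 0 by fry in one direction. The T cell, B cell, NK, ciliated, cardiomyocyte, endothelial, immediate early and thymocyte lists were called without each library in turn, but with the ciliated score as a covariate the B cell (camera adjusted p = 0.481), endothelial (0.799) and thymocyte (0.327) lists were not.

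In S1pr1 KO against C3 KO, which sets the knockouts against each other, lymphocyte, airway and heart muscle lists were called. The same S1pr1 KO libraries enter the comparison with WT, so directions shared with it are not independent. T cell genes were lower in 27 of 28 members (median -0.92, 24 down adjusted over the list alone), with Cd6 at -1.82 (SE 0.35) and Cd4 at -1.13 (SE 0.19). The list was called by camera (adjusted p = 1.94e-20, adjusted p = 0.608 with an estimated correlation). B cell genes were lower in 20 of 21 members (median -1.18, 13 down adjusted over the list alone, camera adjusted p = 3.89e-10). NK genes were higher in all 19 members (median 0.67, 8 up adjusted over the list alone, camera adjusted p = 1.69e-09), with Klra8 at 1.66 (SE 0.37) and Gzmb at 1.18 (SE 0.31). Ciliated genes were higher in all 28 members (median 0.35, 1 up adjusted over the list alone, camera adjusted p = 2.98e-10), with Ccdc153 at 0.80 (SE 0.16). Cardiomyocyte genes were higher in 23 of 24 members (median 1.19, 21 up and 1 down adjusted over the list alone, camera adjusted p = 6.54e-09), with Tnni3 at 1.20 (SE 0.36) and Nppa at 5.08 (SE 1.25), or 2.48 without the library labelled S1pr1 KO 2. For the latter 4 lists adjusted p = 0.675 with an estimated correlation. Exact permutation of the list scores gave p = 0.0286 for NK, 0.0571 for T cell, B cell and cardiomyocyte, and 0.0857 for ciliated genes.

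No gene passed in this comparison. The genes of lowest p were Scart1 (2.11, SE 0.27), the matricellular protein gene Thbs3 (-0.65, SE 0.09), Nipsnap2 (0.31, SE 0.05), elastin Eln (-0.68, SE 0.10) and the chromatin protein gene Hmgb1 (0.39, SE 0.06), each with edgeR adjusted p = 0.0582. Against WT, Thbs3 fell in S1pr1 KO by 0.62 (SE 0.09, edgeR adjusted p = 0.0145), Hmgb1 rose by 0.44 (SE 0.06, edgeR adjusted p = 0.0145) and Nipsnap2 rose by 0.30 (SE 0.05, edgeR adjusted p = 0.0171), while Eln (-0.11, SE 0.10) did not pass and was at -0.19 without WT 2, -0.17 without S1pr1 KO 3, -0.056 without WT 4 and -0.045 without S1pr1 KO 1. S1pr1 was at -0.60 (SE 0.29), -1.08 without the library labelled S1pr1 KO 2 (edgeR adjusted p = 0.111) and -1.08 without that library and WT 2, where it passed (edgeR adjusted p = 0.0113). C3 was at 0.15 (SE 0.30) and ranged from -0.029 without C3 KO 2 to 0.67 without the library labelled C3 KO 4, and S1pr4 was at -0.80 (SE 0.13, edgeR adjusted p = 0.0693). The edgeR test called 0 genes and 2437 had an unadjusted p under 0.05. DESeq2 called 293 (152 up, 141 down), limma voom with quality weights 36, and limma on log2 FPKM 7 and 6 with pseudocounts of 1 and 0.1. Without 1 library the count was 13 without C3 KO 1, 4 without C3 KO 3, 12 without the library labelled C3 KO 4, 1 without the library labelled S1pr1 KO 2, 8 without S1pr1 KO 3 and 0 without any of the other 7.

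Of the 42 lists, 24 were called in S1pr1 KO against C3 KO (11 up, 13 down), 0 with an estimated correlation, where the lowest adjusted p was 0.608, and 0 by fry in one direction. Lower lists besides the T and B cell lists were erythroid (18 of 19 members, median -1.27, camera adjusted p = 0.000273), with Hbb-bt at -2.75 (SE 0.96) and Slc4a1 at -3.91 (SE 1.30), or -0.47 and -1.48 without C3 KO 3, alveolar type 1 (15 of 19, -0.06, 0.00556), with Col4a3 at -0.31 (SE 0.07), and alveolar macrophage (17 of 23, -0.23, 0.00707), with Ccl6 at -0.73 (SE 0.19) and Marco at -0.89 (SE 0.31), or -0.39 without the library labelled C3 KO 4. So were, with members, median and camera adjusted p in that order, inflammasome (21 of 25, -0.17, 0.00250), thymocyte (9 of 12, -0.60, 0.00429), immediate early (19 of 28, -0.29, 0.00879) and alveolar type 2 genes (19 of 23, -0.13, 0.0164). The same held for neutrophil (21 of 22, -0.93, 0.0390), S1P and ceramide (25 of 37, -0.07, 0.0440), endothelial (23 of 34, -0.10, 0.0470) and mesothelial genes (12 of 14, -0.14, 0.0470). Higher lists besides those above were mammary epithelial (23 of 27 members, median 0.37, camera adjusted p = 0.00112), with Esr1 at 0.66 (SE 0.13) and the casein Csn3 at 2.94 (SE 1.24), skeletal muscle (13 of 13, 1.41, 0.00475), with Acta1 at 5.70 (SE 2.36), or 0.83 without the library labelled S1pr1 KO 2, and smooth muscle and pericyte (17 of 22, 0.13, 0.0184), with Rgs5 at 1.01 (SE 0.24). Also higher, in the same order of values, were proliferation (36 of 40, 0.24, 0.00153), club cell (19 of 22, 0.34, 0.00372), interferon response (26 of 34, 0.19, 0.00773), mitochondrial (9 of 13, 0.18, 0.0195) and adipocyte genes (15 of 19, 1.22, 0.0445). For these 19 lists adjusted p = 0.608 to 0.677 with an estimated correlation, and exact permutation of their scores gave p = 0.0571 to 0.629. Adjusted over the list alone, 2 alveolar type 1, 5 thymocyte and 1 S1P gene fell, 1 mammary, 1 smooth muscle, 1 neutrophil and 1 thymocyte gene rose, and the other 13 of these lists had 0.

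The T cell, B cell, NK, ciliated, cardiomyocyte, inflammasome, mammary and thymocyte lists were called without each library in turn in S1pr1 KO against C3 KO, and the others were not. Camera adjusted p rose past the threshold without WT 1 for endothelial genes (0.0508) and without WT 3 for adipocyte (0.0528), endothelial (0.0541), neutrophil (0.0541) and mesothelial genes (0.0634). Without C3 KO 1 it did so for interferon (0.0679), immediate early (0.114) and endothelial genes (0.149), and without C3 KO 2 for neutrophil (0.0721), S1P (0.0799), adipocyte (0.144) and endothelial genes (0.616). Without C3 KO 3 it did so for club cell (0.0576), endothelial (0.0749), S1P (0.0974), adipocyte (0.149), mitochondrial (0.153), erythroid (0.232), mesothelial (0.270) and neutrophil genes (0.945). Without the library labelled C3 KO 4 it did so for interferon (0.176), mitochondrial (0.201), mesothelial (0.287), immediate early (0.351), alveolar macrophage (0.383), smooth muscle (0.383) and alveolar type 2 genes (0.403). Without S1pr1 KO 1 it did so for S1P (0.0650), mitochondrial (0.0929) and mesothelial genes (0.325), and without the library labelled S1pr1 KO 2 for endothelial (0.0976), mitochondrial (0.101), smooth muscle (0.101), skeletal muscle (0.280), neutrophil (0.533) and adipocyte genes (0.816). Without S1pr1 KO 3 it did so for adipocyte (0.0660), endothelial (0.0719), mesothelial (0.0768), S1P (0.0779), proliferation (0.114), alveolar type 1 (0.141), immediate early (0.191), alveolar type 2 (0.209) and interferon genes (0.281). Without S1pr1 KO 4 it did so for immediate early (0.0857), alveolar type 1 (0.0923), S1P (0.0930), endothelial (0.202), mesothelial (0.230) and proliferation genes (0.247). The number of called lists was 15 without S1pr1 KO 3.

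Other settings also ended list calls in S1pr1 KO against C3 KO. With a filter of 1 CPM in 4 libraries these were S1P (camera adjusted p = 0.0519), endothelial (0.0559), mesothelial (0.0693) and neutrophil genes (0.0843), and with RLE factors mesothelial genes (0.0521). With genes of 1 list only they were neutrophil (0.0514), endothelial (0.0959), adipocyte (0.110) and thymocyte genes (0.977). With the ciliated score as a covariate they were proliferation (0.0710), thymocyte (0.222), club cell (0.315), adipocyte (0.421), inflammasome (0.449), S1P (0.449), erythroid (0.546), mesothelial (0.856), endothelial (0.865) and neutrophil genes (0.865). With the cardiomyocyte score they were S1P (0.0558), alveolar type 2 (0.202), immediate early (0.245), mitochondrial (0.245), endothelial (0.366), inflammasome (0.453), club cell (0.935), skeletal muscle (0.935), smooth muscle (0.935) and neutrophil genes (0.997).

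Both knockouts were compared with the same WT libraries. The 2 genes called in both were Gm28438, up in both, and mt-Nd3, down in both, where independent lists of these sizes would share 0.00821 rising and 0.00534 falling genes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.560, against a mean of 0.501 and a maximum of 0.515 in 50 simulations of unchanged groups against shared controls. In those simulations 0 genes were called in both. The covariance of the log2 fold changes was 0.115 against a simulated 0.0381, a difference of 0.0766, and 69.8% of genes had the same sign against a simulated 66.6%. The simulations drew each gene independently, without the co-variation of genes in real libraries. Their spread may therefore be too narrow, and values past their maximum do not show a shared effect of the knockouts. With the WT libraries split so that each knockout was compared with 2 of its own, the mean r over the 6 ways was 0.203, the mean covariance was 0.0693 and the shared calls were 0 to 1. The shared count was 1 without WT 1, WT 2, WT 3, WT 4, S1pr1 KO 1, S1pr1 KO 3, S1pr1 KO 4 or the library labelled S1pr1 KO 2, and 29 without the library labelled C3 KO 4. DESeq2 called 73 genes in both.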

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

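The tests of shared pseudogene reads and of strain variants in this part were chosen after the results were seen. A library was singled out where it lay far from the other 3 of its group relative to the range of the group, which chance does in about 1 in 20 groups. For list scores this held in 9 of 126 groups, where chance gives 6.3, and for the levels of named genes in 31 of 273 groups, where chance gives 13.7. Many named genes belong to the same lists, so these counts are not independent. The library labelled C3 KO 4 was singled out 9 times, the library labelled S1pr1 KO 2 8 times, WT 1 and C3 KO 3 5 times each, and S1pr1 KO 3 4 times.

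Among list scores (mean log2 CPM), the library labelled C3 KO 4 stood apart for B cell genes (2.97, others 4.32 to 4.40), dendritic cell genes (4.16, others 3.65 to 3.72) and extracellular matrix genes (6.31, others 6.54 to 6.58). The library labelled S1pr1 KO 2 stood apart for skeletal muscle (4.27, others 0.45 to 1.08), smooth muscle and pericyte (5.97, others 5.75 to 5.78) and dendritic cell genes (3.57, others 3.82 to 3.86). Within S1pr1 KO, B cell genes were at 3.93 in S1pr1 KO 3 (others 2.53 to 2.71) and fibroblast genes at 6.66 in S1pr1 KO 1 (others 6.57 to 6.58). Club cell genes were at 5.65 in WT 1 (others 6.64 to 6.74).

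Among genes, the library labelled C3 KO 4 stood apart within its group for C3 (1416 CPM), Abca17 (4.53 CPM), Cd79a (11.8 CPM), Atp6v0c-ps2 (32.7 CPM), Rnps1-ps (11.9 CPM) and Tdg-ps2 (3.86 CPM). The library labelled S1pr1 KO 2 did so for S1pr1 (366 CPM), Acta1 (64.5 CPM), Myh1 (28.2 CPM), Nipsnap2 (83.6 CPM) and Nppa (329 CPM). C3 KO 3 stood apart for Hbb-bt (4556 CPM), Hbb-bs (10399 CPM), Hba-a1 (7405 CPM), Slc4a1 (130.1 CPM) and Nlrp3 (16.2 CPM). In WT 1 these were Hbb-bt (269.7 CPM), Slc4a1 (8.19 CPM), Hamp (0.866 CPM) and Mlf1 (6.55 CPM), and in WT 2 they were Acta1 (98.6 CPM) and Myh1 (55.0 CPM). S1pr1 KO 3 stood apart for Cd79a (26.9 CPM), Cd8b1 (3.16 CPM) and Rnps1-ps (0.398 CPM). Single genes were Pgr in WT 4 (4.31 CPM) and C3 KO 2 (10.1 CPM), Nppa (7.49 CPM) and Rpl34-ps1 (27.6 CPM) in C3 KO 1, Zfp36 in S1pr1 KO 1 (547 CPM) and S1pr4 in S1pr1 KO 4 (14.1 CPM).

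In 41 of 53 large changes of S1pr1 KO against WT the C3 KO libraries lay on both sides of the midpoint between the WT and S1pr1 KO levels (mean log2 CPM); in 23 of these 41 all 4 C3 KO libraries lay within 0.25 of that distance from one of the levels, while in others, such as Kcnj3 and Kcng2, they lay between. Shared reads were tested on pseudogenes named after a parent gene. The parent moved the other way in 9 of 11 pairs, all but Rps6-ps4 and Glo1-ps. The median ratio of parent change to opposite pseudogene change was 0.935. This may point to reads passing between copies but missed the 90% of pairs set as the mark, so it remains open. By library, Atp6v0c-ps2 and its parent Atp6v0c were at 32.7 and 86.7 CPM in the library labelled C3 KO 4. In the other C3 KO libraries they were at 0.322 to 0.578 and 107.6 to 114.8 CPM. A strain variant carried by part of the mice was tested by whether called genes within 10 Mb had the same C3 KO libraries on the same side of the midpoint: near pairs matched in 84.4% against 51.5% for pairs on other chromosomes, a difference of 32.9 percentage points (permutation p = 0.0025, 10000 permutations). That met the mark first written, but 5 of the 8 near pairs came from 4 genes on chromosome 17 and the other 3 pairs matched in 58.3%. A requirement for pairs elsewhere was added after this was seen, and the explanation is left open. Each pseudogene was placed at its own position, while Atp6v0c and Rnps1, parents of Atp6v0c-ps2 and Rnps1-ps on chromosome 6, lie on chromosome 17. Pairs by the position of a parent gene were not tested. In mt-Nd3 and Gm28438 all 8 knockout libraries differed from all 4 WT libraries, with the sum of both at 6.04 to 8.39 CPM in WT and 4.84 to 12.3 CPM in the knockouts, and strain background and genotype cannot be told apart for them because no knockout library shared the WT levels.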

How the results depend on the processing

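Counts of called genes are given as C3 KO against WT, S1pr1 KO against WT, and S1pr1 KO against C3 KO, beside 2, 274 and 0 in the edgeR fit. DESeq2 called 155, 1224 and 293, limma voom 21, 928 and 36, and limma on log2 FPKM 6, 171 and 7 with a pseudocount of 1 and 6, 150 and 6 with 0.1. Without a filter S1pr1 KO against C3 KO gave 15, fits of 2 groups gave 1 for C3 KO against WT, and a fold threshold of 1 on the log2 scale gave 130 for S1pr1 KO against WT. In C3 KO against WT and S1pr1 KO against WT, the proliferation covariate gave 1 and 66, and the mammary covariate gave 30 in the latter. Chosen after seeing the data were the covariates for ciliated and cardiomyocyte scores, protein coding genes alone and the pairs of libraries left out: the ciliated covariate gave 1 and 37, the cardiomyocyte covariate 1 in S1pr1 KO against WT, and protein coding genes alone 0, 180 and 1, where fewer genes were tested. With the library labelled C3 KO 4 and the library labelled S1pr1 KO 2 both left out the counts were 31, 473 and 3, and with WT 2 and the library labelled S1pr1 KO 2 both left out 1, 10 and 2. Leaving out each library in turn gave 1 to 32, 2 to 571 and 0 to 13. Except for fewer genes or libraries, the cause was not tested.

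Called lists numbered 6, 15 and 24, and 0 in each comparison by camera with an estimated correlation or by fry in one direction. The test of fry for changes in either direction called 1, 8 and 4. The ciliated covariate gave 3 and 9 in C3 KO and S1pr1 KO against WT, the cardiomyocyte covariate 14 in S1pr1 KO against C3 KO, and WT 2 with the library labelled S1pr1 KO 2 left out 3 in C3 KO against WT. Leaving out each library gave 3 to 11, 12 to 17 and 15 to 25. Genes called in both knockouts, 2, numbered 73 by DESeq2, 27 without the library labelled C3 KO 4 and the library labelled S1pr1 KO 2, 1 without WT 2 and the library labelled S1pr1 KO 2, 0 to 1 with the WT libraries split, and 1 to 29 leaving out each library. The cause was not tested.

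C3 in C3 KO against WT was -0.77 and past the threshold without the library labelled C3 KO 4 and the library labelled S1pr1 KO 2, and ranged from -0.77 to -0.072 leaving out each library. S1pr1 in S1pr1 KO against WT was past the threshold by limma voom (-1.17), without both of those libraries (-1.33) and without WT 2 and the library labelled S1pr1 KO 2 (-1.14), and ranged from -1.33 to -0.66 leaving out each library. Over the other alternatives, covariates included, C3 in C3 KO ranged from -0.77 to -0.24 and S1pr1 in S1pr1 KO from -1.73 to -0.59.

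Genes turned in sign only among those that were not called. In C3 KO against WT these were C5ar1 (-0.049 by limma voom, -0.050 without WT 3, -0.19 without C3 KO 3, and -0.19 to 0.20 over the libraries left out) and Nlrp3 (-0.011 without WT 3, -0.16 without C3 KO 3, and -0.16 to 0.27 over the libraries left out). In S1pr1 KO against WT the ciliated covariate turned C3ar1 (0.0077), C5ar1 (0.33), Nlrp3 (0.23) and Eln (0.016), and the cardiomyocyte covariate turned Il1b (0.070). C3ar1 was 0.018 without WT 1, 0.096 without WT 4 and 0.048 without S1pr1 KO 1, and ranged from -0.18 to 0.096 over the libraries left out. In S1pr1 KO against C3 KO the mammary covariate turned Csn3 (-0.092). C3 was -0.048 with the ciliated covariate, -0.022 without C3 KO 1 and -0.029 without C3 KO 2, and ranged from -0.029 to 0.67 over the libraries left out. The cause was not tested.

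Over all alternatives, values of called genes named in the text stayed on their side of the threshold 723 times and lost it 481 times, with 0 turned in sign. Values of genes not called stayed so 1993 times, passed 96 times and turned 17 times. Over all genes the fixed rule allows these were 548, 403 and 0, and 6148, 141 and 35.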

Other observations

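The tests of the NK score, of airway and heart muscle as covariates (including its separation into T, NK and B cell genes) and of proximal lung were chosen after the results were seen, while the other splits and the tests around the targeted genes were not. Trdc, the constant chain of the gamma delta T cell receptor, rose in S1pr1 KO by 1.75 (SE 0.27, edgeR adjusted p = 0.0145), from 0.85 to 1.46 CPM in the WT libraries to 2.71 to 4.45 CPM in S1pr1 KO. Scart1, a scavenger receptor found on gamma delta T cells, rose by 2.39 (SE 0.27, edgeR adjusted p = 0.00716) while Cd4 fell by 1.10 (SE 0.19, edgeR adjusted p = 0.0276). Of 11 other genes used in gamma delta T cells that were looked up after this was seen, 7 were tested and 0 were called in edgeR, the lowest adjusted p being 0.224.

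T and B cell lists were lower and the NK list higher in S1pr1 KO than in WT by camera with the preset correlation (adjusted p = 0.645 for T cells and 0.710 for B cells and NK cells with an estimated correlation). A lower share of all immune cells would lower NK genes too, but all 19 were higher. The NK score was 2.47 to 2.79 in S1pr1 KO against 1.11 to 2.23 in WT, a difference of 0.80. An equal fall of all immune cells alone would not give this. The NK rise is part of the pattern to be explained and was known beforehand, so its test adds no separate support. More airway or heart muscle in the sampled piece was tested with the ciliated and the cardiomyocyte score as covariates, in that order: the T cell score difference of -0.93 (SE 0.27) became -0.36 (SE 0.33) and -0.75 (SE 0.40), that of B cells went from -1.06 (SE 0.43) to -0.17 (SE 0.53) and -0.95 (SE 0.65), and that of NK cells from 0.80 (SE 0.34) to 1.70 (SE 0.31) and 1.06 (SE 0.49). Camera with the preset correlation still called T cells lower (highest adjusted p = 0.00465) and not B cells (0.481), but of the corrected differences only that of NK cells with the ciliated score had a 95% interval clear of 0, a requirement added after the calls were seen, so this explanation stays open. The S1pr1 genotype may underlie the pattern, which remains a hypothesis not tested here, as is any strain background that goes with it.

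Cardiomyocyte and ciliated cell lists were both higher in S1pr1 KO than in WT by camera with the preset correlation (adjusted p = 0.710 and 0.678 with an estimated correlation). A piece with more proximal lung, holding large airways and veins, could raise both, and within groups their scores would then rise together. Over the 12 libraries centred within groups Pearson r was 0.153 (permutation p = 0.637) and Spearman rho 0.0699 (permutation p = 0.846), and r was -0.19 without the 2 libraries farthest from the median. This neither excludes nor bears out unequal sampling, which stays open beside the genotype, which was not tested.

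Other splits of the 8 libraries of a comparison into groups of 4 were counted among 35. In C3 KO against WT 2 splits, the real one included, gave at least the 2 genes of the real split, with 12 as the highest of the others, so chance cannot be excluded. In S1pr1 KO against WT only the real split (1 of 35) gave as many as its 274 genes, the highest of the others being 3. With 35 splits no result can be rarer than 1 of 35, so this argues against chance but does not exclude it. Every other split mixed both groups, so a fixed difference between them, whatever its cause, can lower the other counts. In S1pr1 KO against C3 KO the real split gave 0 genes, which any of the 35 must reach, so the count says nothing about chance. The highest of the others was 46, for C3 KO 1, C3 KO 2, C3 KO 3 and S1pr1 KO 3 against the rest. Counts above the real one, as the 12 and the 46, can point to a structure of the samples. Both were the highest of 35 splits picked after they were seen, and no such structure was tested.

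Called genes were not concentrated within 10 Mb of the targeted genes, as a carried chromosome segment of other strain origin could make them. Near C3, 0 of 148 genes were called in C3 KO against WT (Fisher's exact odds ratio 0, 95% interval 0 to 715). Near S1pr1, 2 of 155 genes were called in S1pr1 KO against WT, against 272 of 20074 elsewhere (odds ratio 0.952, 95% interval 0.114 to 3.53). An odds ratio of at most 1 had been set as the mark against such a segment, but both intervals reach well above 1, so the tests exclude nothing.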
